A study of Homo sapiens with 2 samples.

How the data were processed

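Total RNA from GFP-sorted REH cells was sequenced as 2 libraries, 1 from cells with doxycycline-inducible PAX5-IRES-GFP and 1 from cells with inducible IRES-GFP. RNA was extracted with a QIAGEN RNeasy kit and libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols. The deposited files hold raw counts of reads per gene, as whole numbers, with the gene's Entrez number and a length in bases. The authors counted reads with featureCounts on hg19 (GRCh37), per the submitters' processing notes. The version of featureCounts, the aligner, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Without a known strand setting, reads of overlapping or antisense genes cannot be told apart, and near-identical gene copies may have exchanged reads or lost them. The table of the whole series and the files of the 2 libraries held the same 51404 values. Each column of the series table carries the library number that also names the file of that library, and was matched to its group by that number.

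Groups came from the genotype labels. Gene symbols were taken by Entrez number from a RefSeq table of GRCh38.p14, used for names and for which genes neighbour each other. No coordinates are printed, because the counts were made on another build. Of 25702 features, 23696 matched a symbol. The 2006 others held 0.519% of the PAX5 counts and 0.590% of the control counts and stayed in the totals.

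Libraries were scaled by TMM in edgeR 4.0.16 (R 4.3.3), with factors of 0.9954 for the PAX5 library and 1.0046 for the control library. CPM (counts per 1000000) and log2 ratios used the scaled library sizes. With 1 library per group there are no residual degrees of freedom, so neither edgeR nor DESeq2 could test a gene, and a fixed rule of size took the place of a test. Each ratio has an exact Clopper-Pearson 95% interval, conditional on the gene's total count, from scipy 1.17.1. These intervals and the floors below cover counting error only, because reads amplified by PCR are not independent molecules and variation between cultures is not measured. A gene was called higher or lower when the bound nearest 0 lay at or beyond 2-fold and the 2 libraries together had at least 10 counts. Where a library had 0 counts, it was set to a floor of 3 counts and the fold is given as "at least" that value. The interval bound that the rule uses also covers the counting error of the other library and lies lower, at 107-fold for CREG2. The log2 interval reached 2.12 to each side at 10 summed counts, 0.60 at 100, 0.18 at 1000 and 0.057 at 10000, so differences of weakly expressed genes are much less certain than those of abundant ones.

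Before the data were examined, 41 gene lists of B-lineage, other blood lineage, cell cycle, metabolic, stress and signalling genes were fixed, with 661 genes in all, of which 660 were found. A list's median log2 ratio over members with at least 10 counts was set against 10000 random lists of the same size, matched in 20 bins of mean expression. A list of at least 5 members stood apart when its percentile was under 2.5 or over 97.5, which 5% of lists of independently drawn genes do by chance. This describes these libraries and is not a test of the conditions. The genes named are PAX5, the 12 genes with a symbol and the largest bound on each side, up to 4 members of each list with the largest bound in the direction of its median, and any other member past the rule. Other list members are named with their values as not past it. The values of 1 list member are not reported here, and it is left out of the plot of list members, while the list values include it.

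The rule and the lists were tested on simulated data with the libraries' own levels and sizes. For this comparison, 200 changed genes among 13529 were recovered in 87.0% of cases at 4-fold with 0 false calls, and among 13541 in 98.0% at 8-fold with 1 false call. The intervals held the true value for 95.6% and 95.8% of genes, and 7 and 12 of 200 unchanged lists were called apart. The simulation drew independent counts with counting error only, the model that the intervals assume. These rates therefore check the calculation and do not cover variation between cultures, trends with gene length or genes that move together.

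Alternatives fixed beforehand were scaling by total counts, by DESeq2 1.42.0 size factors and by upper-quartile factors, no count minimum or one of 50, a point ratio or a bound at 1.5-fold or 4-fold, an assumed biological coefficient of variation of 0.1 or 0.2, and the files of single libraries. For lists they were the mean, 10 bins, matching on length as well, and leaving out PAX5 or members past 4-fold. PAX5 is a member of none of the lists, so leaving it out changes only the genes drawn for random lists and is no check of a list's median. Centring on GC content and length (10 by 10 bins, GC content from GENCODE transcripts, matched for 94.3% of tested features) and thinning of the PAX5 library were added after the data were seen.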

Results

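RNA was sequenced from REH cells, a human B-cell precursor acute lymphoblastic leukaemia line (labelled REH-R here), in which doxycycline switched on an introduced cassette. The cassette of one culture carried PAX5, the transcription factor that commits lymphoid progenitors to the B lineage, followed by an internal ribosome entry site (IRES) and green fluorescent protein (GFP). The cassette of the control culture carried the IRES and GFP alone. Both cultures received doxycycline at 1 µg/mL for 3 days, and GFP-positive cells were sorted before RNA extraction. There was 1 library per group, so no difference below has a replicate check, and no p-value or standard error is given. The deposited counts summed to 11944765 in the PAX5 library and 10997864 in the control library. Of 25702 gene features, 16420 had at least 1 count in the PAX5 library and 15999 in the control library, and 13532 had at least 10 counts over both libraries. Ratios are given as the PAX5 library over the control library with an exact 95% counting interval, which covers counting error only and compares these 2 libraries, not the conditions.

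PAX5 itself (Entrez 5079) was the first check of the labels. It had 8319 counts (699.7 CPM, counts per 1000000 after scaling) in the PAX5 library and 2660 counts (241 CPM) in the control library, a ratio of 2.91-fold (2.78 to 3.04) or 1.54 on the log2 scale (1.48 to 1.60). The control cells therefore also contained PAX5 transcript, and counts per gene do not separate the transcript of the cassette from that of the endogenous gene.

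The comparison asked which other transcripts differed between cells with induced PAX5 and cells with GFP alone. By the rule of size fixed beforehand, a counting bound at or beyond 2-fold, 182 features were higher in the PAX5 library, 7 were lower and 13343 were neither. Of all 13532 features with at least 10 counts, 2527 had intervals above 0 and 2274 below, 35.5% together. An interval off 0 was therefore common, and the counts of such intervals given for lists below are to be read against that share. For lists of abundant genes the share is too low a measure, because their intervals are narrow. The log2 interval reached 0.18 to each side at 1000 summed counts and 0.057 at 10000. The median absolute log2 ratio of features with at least 1000 counts was 0.13. Among 24 housekeeping genes, 6 had intervals above 0 and 11 below. Of the 182, 110 had less than 1 CPM in the control library and 43 had 0 control counts. The bound lay at or beyond 4-fold for 70 higher and 2 lower features, and at or beyond 8-fold for 36 higher features and 1 lower feature. Among 5339 features with at least 1000 counts over both libraries, 97.1% had a ratio within 1.5-fold and the SD of the log2 ratio across features was 0.25, so most abundant transcripts were at similar levels in the 2 libraries.

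The 12 genes with the highest bounds encode proteins of several kinds, and each had at most 5 counts in the control library. CREG2 (Entrez 200407) had 426 counts against 0, at least 132-fold higher over the floor of 3 counts, with a lower interval bound of 107-fold. MYH14, a non-muscle myosin heavy chain (Entrez 79784), had 667 against 3 counts, 207-fold (70.4 to 1004). TNFRSF8, which encodes the activation marker CD30 (Entrez 943), had 503 against 2 counts, 234-fold (64.4 to 1935). MYBPC2, a myosin-binding protein of fast skeletal muscle, had 639 against 5 counts, 119-fold (50.6 to 367). DIO3, a deiodinase that inactivates thyroid hormone, had 199 against 0 counts, at least 61.6-fold higher over that floor (lower interval bound 49.7). TCL1B, a relative of the TCL1A oncogene, had 187 against 0 counts, at least 57.9-fold higher over the floor (lower interval bound 46.6). MYO7B, an unconventional myosin, had 373 against 2 counts and the water channel AQP8 had 263 against 1. The Wnt ligand WNT4 had 286 against 3 counts, 88.6-fold (30.0 to 432), and the transcription factor MAF had 163 against 2, 75.7-fold (20.6 to 631). The receptor tyrosine kinase EPHA2 (102 against 0 counts) and the prostacyclin synthase PTGIS (100 against 0 counts) were at least 31.6-fold and at least 31.0-fold higher over the floor. Their lower interval bounds were 25.2-fold and 24.7-fold.

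**Figure D1:**
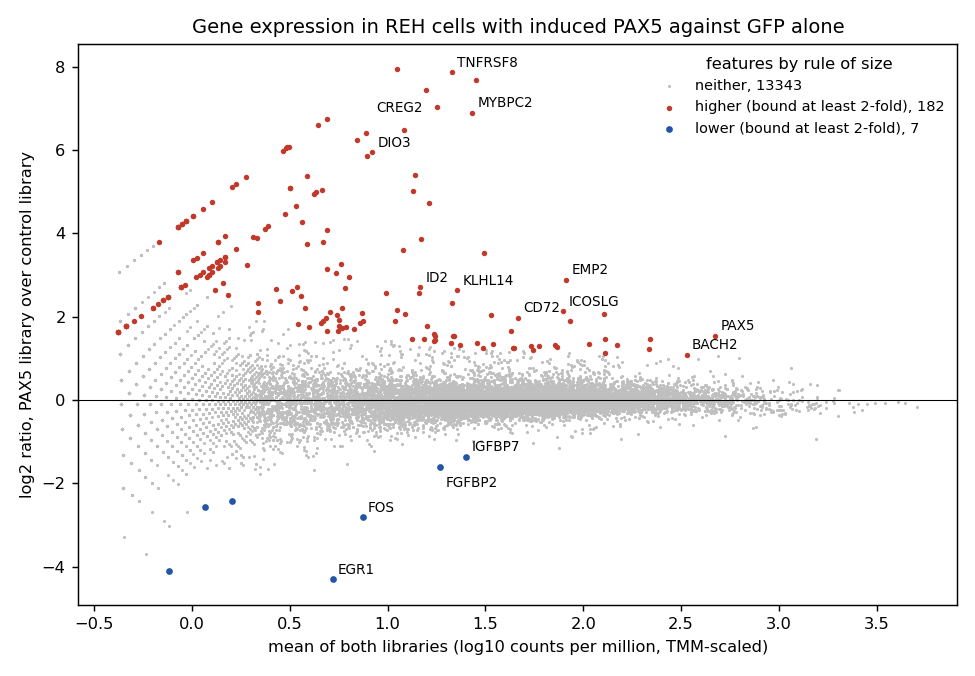
Each point is a feature with at least 10 counts over both libraries, placed by its mean level (x axis, log10 CPM) and its log2 ratio of the PAX5 library over the control library (y axis). A library with 0 counts was set to 3 counts, and the 182 higher and 7 lower features are coloured, with 110 of the higher ones under 1 CPM in the control library.

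Of the 7 lower features, 6 had a gene symbol. The immediate early genes EGR1 (6 against 110 counts) and FOS (22 against 144 counts) were 19.7-fold (8.78 to 54.9) and 7.04-fold (4.48 to 11.6) lower in the PAX5 library. The interferon-induced gene IFI44L had 1 against 16 counts, 17.2-fold lower with an interval of 2.67 to 722. FGFBP2 (109 against 309 counts) was 3.05-fold lower and IGFBP7, a secreted growth factor binding protein (168 against 402 counts), was 2.57-fold lower. RPS2P32 had 4 against 22 counts, but it is a ribosomal protein pseudogene whose reads cannot be told from those of its parent gene. The myeloid granule enzyme MPO had 554 against 1138 counts, a log2 ratio of -1.14 (-1.29 to -0.997), and did not pass the rule. The next on this side did not pass it either: the thromboxane receptor gene TBXA2R had 24 against 71 counts and a log2 ratio of -1.67 (-2.40 to -0.99), and the serotonin receptor gene HTR7 had 38 against 102 and -1.53 (-2.11 to -0.98). Of 3 weakly counted features, HOTTIP had 1 against 12 counts and -3.69 (-9.11 to -0.93), LOC100335030 had 3 against 18 and -2.69 (-5.10 to -0.91), and KDM4A-AS1, an antisense gene whose reads are uncertain, had 2 against 15 and -3.01 (-6.18 to -0.91).

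Known PAX5-activated B-lineage genes were higher as a group. Of 14 measured members, 4 passed the rule and all 4 were higher in the PAX5 library: KLHL14 at 6.24-fold (4.83 to 8.15), the B-cell surface protein CD72 at 3.92-fold (3.37 to 4.58), the Ets-family factor SPIB at 3.24-fold (2.21 to 4.86) and the transcription factor BACH2 at 2.13-fold (2.03 to 2.24). IRF4 (log2 ratio 1.06), IRF8 (1.04) and CIITA (0.64) had intervals above 0 but did not pass the rule. Other members of the same list did not share this direction: EBF1 had a log2 ratio of 0.01 and CD79A of -0.02, and BLNK (-0.23) and NEDD9 (-1.11) had intervals below 0. The median log2 ratio of the list was 0.71, at percentile 100.0 of 10000 random lists matched on expression.

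Mature B-cell surface markers had 4 of 12 measured members past the rule, all higher in the PAX5 library. They were CD72, the tetraspanin CD37 at 2.57-fold (2.10 to 3.16), the BAFF receptor gene TNFRSF13C at 3.15-fold (2.01 to 5.08) and the chemokine receptor CCR6 with 20 against 1 counts, 18.6-fold (2.97 to 770.3). CD52 was 2.09-fold higher without passing the rule, with a log2 ratio of 1.06, and CD69 had a log2 ratio of -0.47. MS4A1, CR2 and FCER2, markers of later B-cell stages, had 0 counts in both libraries, which allows up to 0.252 CPM in the PAX5 library and 0.272 CPM in the control library. The list's median of 0.12 lay inside the random range at percentile 91.8. It lay above that range when members were averaged by the mean, when random lists were also matched on length, and after centring on GC content and length.

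B-lineage transcription factors had 3 of 22 measured members past the rule, SPIB, BACH2 and ID2, an inhibitor of E-protein DNA binding, which was 6.53-fold higher (4.73 to 9.21). The list's median of 0.11 lay at percentile 97.6, just above the random range, and it lay inside that range under 5 of the alternative settings. Pre-B-cell receptor components did not stand apart (median 0.06, percentile 81.8) and no member passed the rule. Of 17 measured members 7 had intervals above 0, such as IGHM (log2 ratio 0.70), PRKCB (0.59) and CD79B (0.42), and 5 had intervals below 0, such as BLK (-0.54), LYN (-0.27) and IGLL1 (-0.26). V(D)J recombination genes did not stand apart either (percentile 42.8): 4 of 10 members had intervals above 0, with LIG4 at a log2 ratio of 1.03 (0.85 to 1.22), DCLRE1C at 0.47 and PRKDC at 0.46, and 4 had intervals below 0, with DNTT at -0.19 and RAG1 at -0.09. No member passed the rule, and the list's median of -0.03 and mean of 0.13 differed in sign. Plasma cell markers had a median of -0.05 at percentile 34.7 and a mean of 0.34, with CD38 at -0.71 and no member past the rule.

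**Figure D2:**
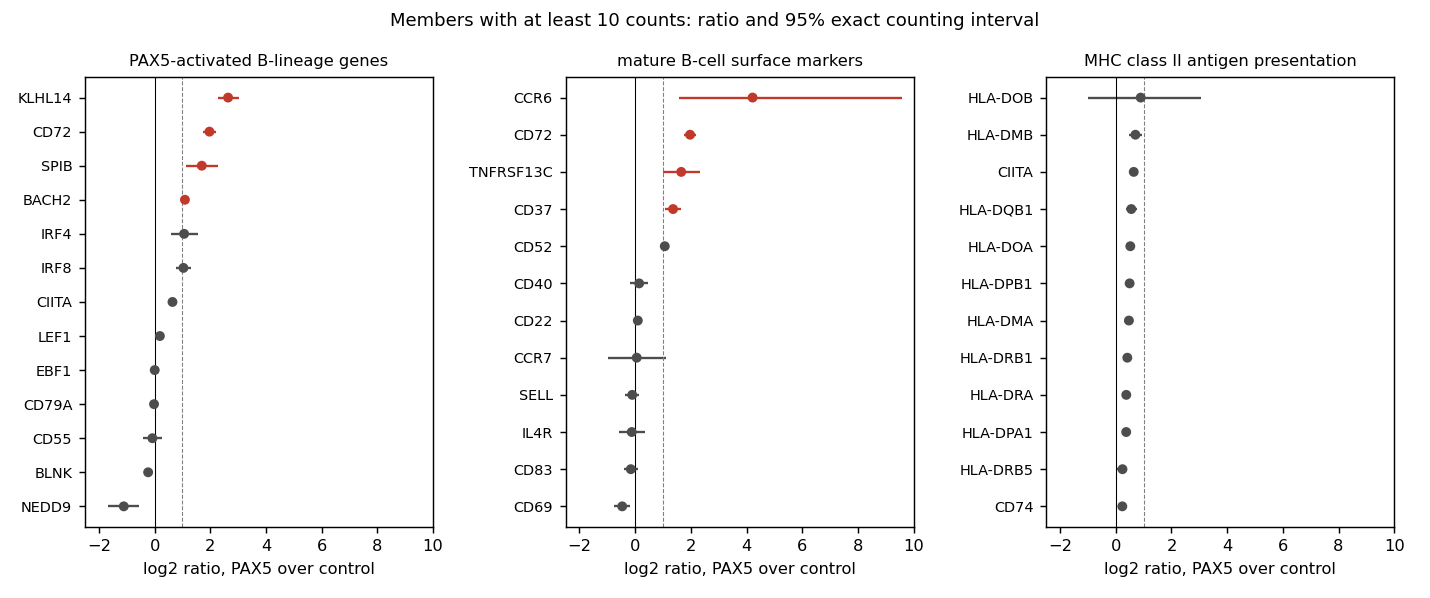
Log2 ratio of the PAX5 library over the control library (points, x axis) with its 95% exact counting interval (lines) for members with at least 10 counts of 3 lists, PAX5-activated genes, mature B-cell surface markers and MHC class II genes. Members past the rule of size are red, the dashed line marks a log2 ratio of 1, and 11 of the 12 MHC class II members have intervals above 0 without reaching it.

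The MHC class II and class I lists both stood apart above their random lists, mostly through members under the rule of size. Of 12 measured MHC class II genes none passed the rule, but 11 had intervals above 0 and none below. CIITA, the transactivator of class II genes, was 1.56-fold higher (1.42 to 1.72) and HLA-DMB 1.63-fold (1.38 to 1.93), while the abundant HLA-DRA had a log2 ratio of 0.38 and CD74 of 0.23. The list's median was 0.48, at percentile 100.0. MHC class I genes had a median of 0.29 at percentile 99.97, with 8 of 13 intervals above 0 and 3 below: NLRC5, the transactivator of class I genes, alone passed the rule at 2.54-fold (2.17 to 2.98), HLA-B (0.37), HLA-E (0.36) and HLA-F (0.38) had smaller log2 ratios, and the immunoproteasome genes PSMB9 (-0.27) and PSMB10 (-0.46) lay on the other side of 0. HLA genes are near-identical copies of one another in part, and the counting could split their reads.

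Genes that PAX5 is known to repress did not stand apart as a group (median -0.05, percentile 28.6), and 0 of 9 measured members passed the rule. The macrophage colony-stimulating factor receptor gene CSF1R had 14 against 41 counts, a log2 ratio of -1.66 (-2.65 to -0.75), FLT3 had -0.40 (-0.48 to -0.31) and EMB -0.30 (-0.41 to -0.19). In the other direction, PRDM1, a plasma cell regulator, had 17 against 4 counts, and the abundant XBP1 had a log2 ratio of 0.37 (0.30 to 0.43). Stem and progenitor markers (median -0.11, percentile 14.6) and myeloid markers (median -0.10, percentile 18.7) also lay inside the random range, and no member of either list passed the rule.

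T-cell markers had a median of 0.49 over 8 measured members, at percentile 99.5, with no member past the rule. BCL11B had a log2 ratio of 1.17 (0.95 to 1.40), CD247 of 1.89 (0.92 to 3.00) and CD4 of 0.67 (0.28 to 1.06). CD3D, CD3G, CD2, CD8A and CD8B had 0 counts in both libraries, and CD3E had 0 counts in the PAX5 library against 1. The list lay inside the random range when the mean replaced the median. Erythroid and megakaryocytic markers (3 measured members) and natural killer cell markers (1 measured member, NKG7, at -0.87) were too few to judge.

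Proliferation genes were at similar levels in the 2 libraries. S phase genes had a median of -0.02 (percentile 25.4) and G2 and M phase genes of -0.01 (percentile 27.2, mean 0.01), with 0 of 24 members of each list past the rule. E2F1 had a log2 ratio of -0.27 and CDC20 of -0.19. Cell cycle inhibitors and quiescence genes had a median of 0.17 at percentile 98.6, with the antiproliferative gene BTG2 at 2.19-fold (1.92 to 2.49), CDKN1B at a log2 ratio of 0.32 and RB1 at 0.23, none of them past the rule. The list lay inside the random range when the mean was used. The p53 targets (median 0.05, percentile 82.4), apoptosis regulators (0.07, percentile 89.9) and histone cluster genes (-0.08, percentile 34.2) did not stand apart.

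Lists of translation, mitochondrial respiration, heat shock and amino acid starvation genes had medians below their random lists, with no member past the rule. Of 24 cytosolic ribosomal protein genes, 22 had intervals below 0 and none above, with a median of -0.26 at percentile 0.0 and RPL37 at a log2 ratio of -0.47. Nuclear oxidative phosphorylation genes had a median of -0.17 at percentile 0.0 and 17 of 22 intervals below 0, with COX6C at -0.32. MYC and ribosome biogenesis targets had a median of -0.16 at percentile 0.03, with the polyamine enzyme gene SRM at -0.54 and MYC at -0.38. Heat shock genes had a median of -0.16 (percentile 0.87) and amino acid starvation genes of -0.12 (percentile 1.72, mean 0.00). Short genes were lower in the PAX5 library in general: when features with at least 100 counts were divided into 10 equal groups by length, from the shortest group (median length 941 bases) to the longest (8295 bases), the median log2 ratio went from -0.20 to 0.19. Across 10424 genes, which are not independent replicates, Spearman's rho was 0.46 with length and -0.16 with GC content. After centring on both properties, MYC and ribosome biogenesis targets still stood apart below and the other lists of this group did not. When random lists were instead matched on length as well as expression, the MYC, ribosomal protein and heat shock lists still stood apart below, and the other lists of the group did not.

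**Figure D3:**
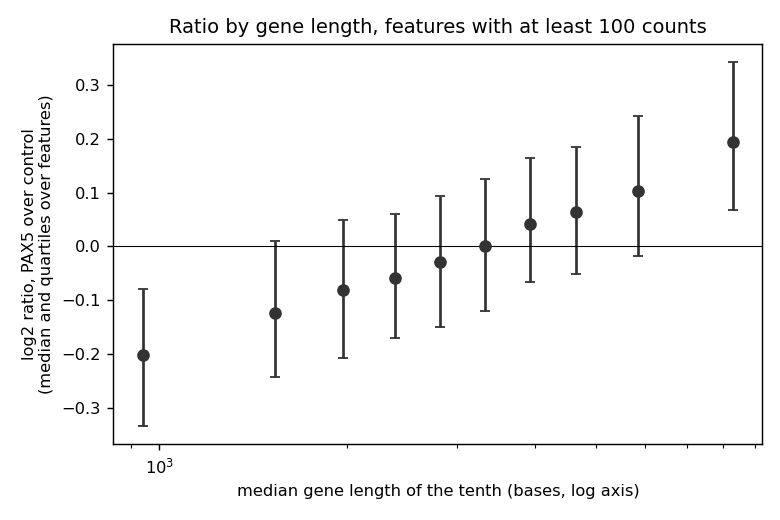
Median log2 ratio of the PAX5 library over the control library (points, with lines from the lower to the upper quartile over features) for 10 equal groups of features with at least 100 counts, placed by median gene length in bases on a log axis. The medians go from -0.20 in the shortest group to 0.19 in the longest.

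Among signalling and metabolic lists, hypoxia response genes stood apart above (median 0.24, percentile 99.97), with ADM at a log2 ratio of 0.46, P4HA1 at 0.37 and 11 of 16 intervals above 0. Notch pathway genes also did (median 0.20, percentile 99.2), with LFNG, a glycosyltransferase that modifies Notch, at 2.06-fold (1.82 to 2.33) and DTX1 at 1.77-fold (1.68 to 1.86). No member of either list passed the rule, and both lists lay inside the random range when the mean was used. The Notch list did so too when random lists were matched on length. Immediate early genes did not stand apart (median 0.13, percentile 94.1) and went both ways. Beside EGR1 and FOS, EGR3 had 10 against 0 counts, at least 3.10-fold higher over the floor of 3 counts, with a lower interval bound of 2.08-fold. DUSP1 had a log2 ratio of 0.57, and the mean of the list was -0.11.

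The TGF-beta and BMP targets had a median of 0.20 at percentile 96.7, with ID2 past the rule and SMAD7 at 2.47-fold (1.81 to 3.42). RAS-MAPK feedback genes (median 0.07, percentile 79.7) included CCND1, which encodes cyclin D1, with 104 against 7 counts, 13.8-fold (6.47 to 35.2). On the other side, the same list included EGR1, 19.7-fold lower. Glucocorticoid receptor and energy-restriction genes (0.05, percentile 77.1) included the cannabinoid receptor CNR2 with 27 against 4 counts, 6.27-fold (2.19 to 24.7), while TXNIP (0.31) and NR3C1 (0.34) were under the rule. ETV6-RUNX1 leukaemia genes (0.11, percentile 94.8) included the telomere-binding factor TERF2 at 2.74-fold (2.52 to 2.98), and adhesion and integrin genes (-0.03, percentile 37.7) included S1PR2 at 2.74-fold (2.11 to 3.58). Interferon response genes (-0.06, percentile 23.1) had IFI44L alone past the rule, and NF-kB targets had a median of -0.04 (percentile 39.1) and a mean of 0.03. Cytokine receptors and STAT5 feedback genes (0.03, percentile 61.1), unfolded protein response genes (0.05, percentile 80.6), cholesterol biosynthesis genes (-0.08, percentile 5.99), glycolysis genes (-0.04, percentile 15.4, mean 0.03) and housekeeping genes (-0.07, percentile 2.96) did not stand apart and had no member past the rule. Of 38 lists judged, 8 stood apart above and 5 below, where 1.9 would by chance if members were drawn independently. Members of a list can move together or share gene length, and several lists share members. The excess over 1.9 is therefore no measure of how many lists differ.

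**Figure D4:**
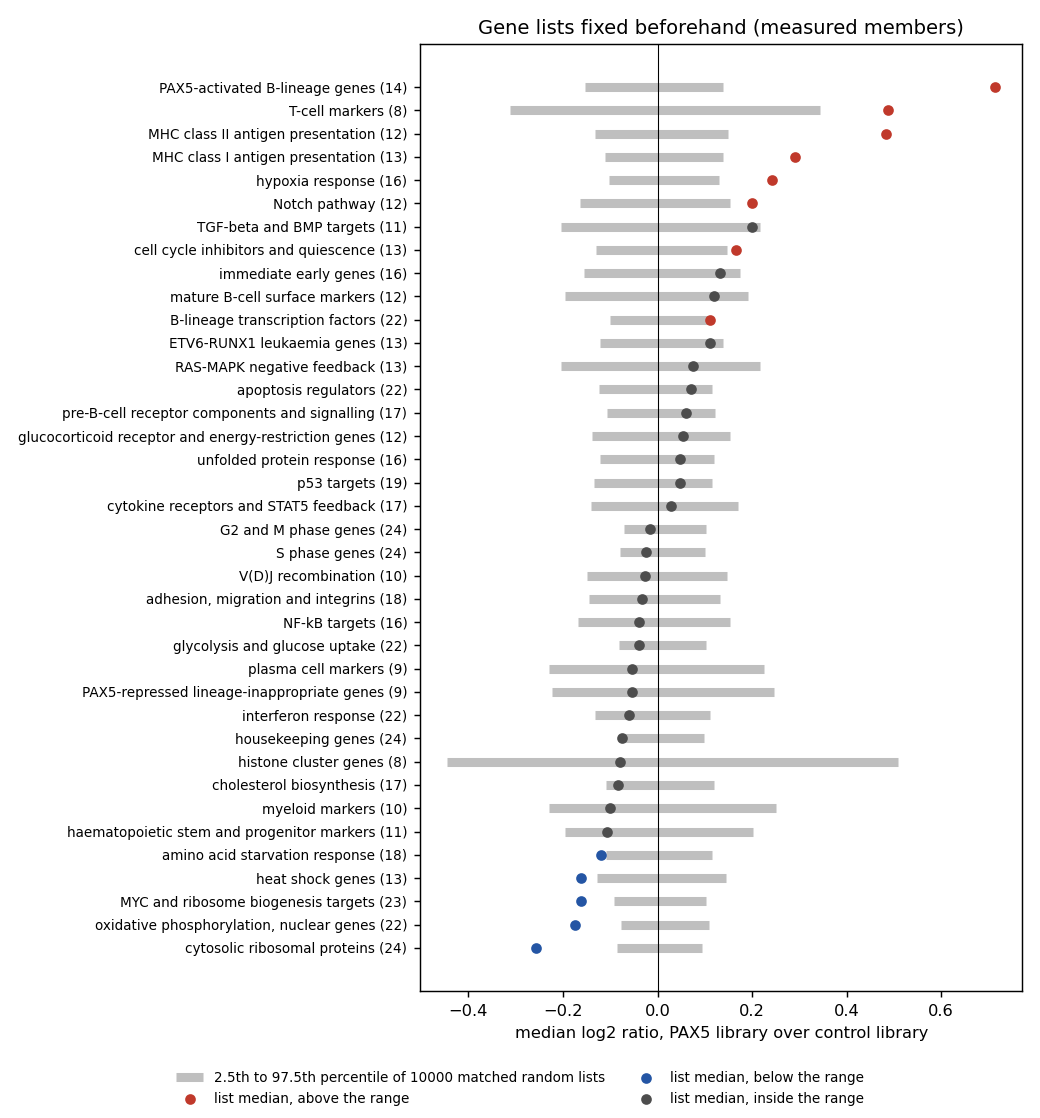
Median log2 ratio of the PAX5 library over the control library (points, x axis) for each of the 38 judged gene lists, with the number of measured members in parentheses. Grey bars span the central 95% of the medians of 10000 random lists matched on expression, with 8 lists above their bars and 5 below.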

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

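Centring on GC content and length and thinning of the PAX5 library were chosen after the data were seen. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Neither the PAX5 ratio nor any list that stood apart changed sign under the alternatives run. Among lists inside the random range, 12 changed sign under at least 1 alternative, for example immediate early genes (from 0.13 to -0.16), plasma cell markers (from -0.04 to 0.32) and V(D)J genes (from -0.01 to 0.13) with means. The log2 ratio of PAX5 stayed inside its counting interval under the other 3 scalings. Counts of higher and lower features stayed within 1.5 times the main 182 and 7 under those scalings, without a count minimum, with an assumed coefficient of variation of 0.1, after centring and after thinning. They were 113 and 4 with at least 50 counts, where fewer genes could be called, 547 and 234 for a point ratio of 2-fold, 355 and 47 for a bound at 1.5-fold and 70 and 2 for a bound at 4-fold, and 3 were lower with an assumed coefficient of variation of 0.2. With upper-quartile factors, which move every log2 ratio by -0.031, BACH2 (log2 bound 1.02) and TNFRSF13C (1.01) no longer reach the rule. MPO, TBXA2R and HTR7 then pass it on the lower side. Over the named genes, 456 values under the other scalings stayed inside the gene's counting interval and 6 left it, all 6 under upper-quartile factors. Each scaling moves every log2 ratio by the same amount, at most 0.031, so these values are not separate checks. Only abundant genes with narrow intervals could leave, and PAX5, with an interval of 1.48 to 1.60, could not.

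List values here are medians, or means where said, minus the centre of the random lists. With at least 50 counts, the B-lineage transcription factors came inside the random range (0.0877) and TGF-beta targets above it (0.24). With means, mature B-cell markers (0.78) and glucocorticoid receptor genes (0.37) came above the range and interferon genes (-0.19) below it, while T-cell markers (0.59), cell cycle inhibitors (0.17), hypoxia genes (0.18), Notch genes (0.29) and amino acid starvation genes (-0.0227) came inside. With 10 bins, B-lineage transcription factors came inside (0.10). With matching on length as well, mature B-cell markers (0.20), immediate early genes (0.17) and TGF-beta targets (0.22) came above, and B-lineage transcription factors (0.0538), Notch genes (0.15), amino acid starvation genes (-0.0702) and oxidative phosphorylation genes (-0.05) came inside, leaving 3 lists below. Without members past 4-fold, B-lineage transcription factors came inside (0.0821) and immediate early genes above (0.24), since EGR1 and FOS were among those left out. After centring on GC content and length, pre-B-cell receptor genes (0.10), mature B-cell markers (0.19), p53 targets (0.11), immediate early genes (0.22) and TGF-beta targets (0.21) came above, and B-lineage transcription factors (0.0614), amino acid starvation genes (-0.0638), heat shock genes (-0.0969), oxidative phosphorylation genes (-0.0514) and ribosomal protein genes (-0.0524) came inside, leaving 1 list below. Except where said, the cause was not tested. Depth limits the weakly expressed genes most, since 110 of the 182 higher features had less than 1 CPM in the control library.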

Other observations

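The tests of scaling and of the shift it would need, of thinning, of abundant lineage transcripts and all lineage markers, of a difference between cultures, of chance placement and shared reads of neighbouring genes, and the split of lists into those above and below were chosen after the results were seen. The genes in the next 2 paragraphs were also chosen after their values were seen.

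Further genes outside the fixed lists were among those higher in the PAX5 library. ICOSLG, the ligand of the T-cell costimulator ICOS, had 1522 against 324 counts, 4.37-fold (3.87 to 4.94). PDGFA had 684 against 55 counts, 11.6-fold (8.77 to 15.5), and the membrane protein gene EMP2 had 1710 against 214, 7.43-fold (6.44 to 8.6). The chemokine gene CCL17 had 81 against 0 counts, at least 25.1-fold higher over the floor of 3 counts, and IL1B had 512 against 201, 2.37-fold (2.01 to 2.80). Among collagen genes COL6A1 had 83 against 4 counts, 19.3-fold (7.25 to 72.4), and COL23A1 had 33 against 0, at least 10.2-fold higher over that floor. COL5A1 had 6121 against 2863 and a log2 ratio of 0.99, under the rule. TP73, a p53 relative, had 56 against 0 counts, at least 17.3-fold higher over that floor. For CCL17, COL23A1 and TP73 the lower interval bound lies below the fold given. EBF3, a relative of the B-lineage factor EBF1, had 21 against 1, 19.5-fold (3.14 to 807).

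The 13 mitochondrially encoded genes were listed with 0 counts in both libraries, a feature of the counting and not a sign of absence. The 8 MTRNR2L genes with enough counts all had intervals below 0, with log2 ratios from -0.86 to -0.30. They are near-identical to mitochondrial ribosomal RNA, so their reads are of uncertain origin.

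The first pattern was that 13 gene lists stood apart from matched random lists while the ratio also followed gene length. After centring on GC content and length 61.5% still did so on the same side, 8 of 13, where under 50% were predicted if the trend were the whole cause, and a first version of the bin medians, seen before they were redefined, also kept 8. Of the lists above, 87.5% still stood apart after centring, and 6 of the 8 did with random lists matched on length, which argues against the trend as the cause of that side. Of the lists below, 20.0% did after centring but 3 of the 5 with the matching on length, among them ribosomal protein and heat shock genes, all with smaller values. A length-dependent difference between the libraries may therefore account for part of that side. The matching used 4 bins of length against 10 in the centring and can leave more of the trend in, so the 2 settings do not weigh equally. The size of that part stays open. Neither side can be tied to PAX5 with 1 library per group.

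The second pattern was that features higher in the PAX5 library outnumbered lower ones, 182 to 7, an excess whose size depends on the rule, with 547 to 234 for a point ratio of 2-fold and 355 to 47 for a bound at 1.5-fold. Without a cut on size, the sides were closer, with 2527 intervals above 0 and 2274 below. Depth is argued against, because thinning the PAX5 library to the control total left a ratio of 17.3. Scaling stays open: the lowest ratio over 4 scalings was 17.5, but these moved log2 ratios by at most 0.031, and a shift of 0.44 would be needed to bring the higher features under 2 times the lower ones. T-cell markers, 1 of the 2 lineage lists that could be judged, stood apart above, as predicted for cells of another blood type. Over all fixed members of 4 lineage lists, the upper quartile of extra counts in the PAX5 library was at most 16.0. The median for the higher features was 71, but these were selected for an excess in that library, so the comparison cannot decide the question. In addition, 21 abundant lineage transcripts had 29 counts against 51, but were picked with their counts known and exclude nothing. Cells of another blood type therefore stay open as a cause. A difference between the 2 cultures other than PAX5 cannot be told apart from PAX5, because each group has 1 library, although PAX5-activated genes lay at percentile 100.0.

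The third pattern was that genes higher in the PAX5 library lay near each other. Of 178 such genes with a known place, 41 had another within 2 positions in gene order, in 18 groups such as TCL6 with TCL1B, DIO3OS with DIO3, KCNJ16 with KCNJ2, COL6A1 with COL6A2 and SPIB with MYBPC2, against a median of 6 and a highest of 22 in 10000 random sets matched on expression. When antisense and overlapping genes were taken out of the gene order, 32 of the 156 higher genes left had such a neighbour, against a highest of 22. This argues against reads shared by antisense or overlapping genes as the whole cause. Reads shared in other ways, as between near-identical copies, were not tested. A gain of DNA copies common to these regions is argued against by the 158 other expressed genes within 10 positions. Pooled over the regions, their log2 ratios had an upper quartile of 0.21, under the 0.58 of 3 copies over 2. A gain in only a few of the regions, or in a shorter stretch, is not excluded by the pooled value. No biological explanation of this pattern was tested.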
